A study of Gallus gallus with 10 samples.

How the data were processed

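Gene expression was measured in whole embryonic chicken hearts on 10 single-colour oligonucleotide arrays, 5 hybridised with RNA pooled from males and 5 with RNA pooled from females. Each sample is taken here as a pool of RNA of 1 sex, and the pools of each sex carry the letters A to E. The sample titles name the arrays' tissue, sex and letter. The embryonic age, the number of embryos in a pool and whether pools shared embryos are not given in the sources used here, so p-values measure the spread between these pools, which may be partly technical.

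The deposited values are linear intensity values per probe set, from 0.724 to 283413. The software and summarisation that the authors used are not given in the sources used here. From the deposited intensity values themselves, the mean after trimming 2% at each end lay between 2500.5 and 2500.6 on every array, so the arrays had been brought to 1 common level, by a method that the values do not show. Array medians ranged from 605 to 735. No detection calls were used here, so signal cannot be separated from background for single probe sets, and the number of arrays limits the precision. No array's values were identical to another's, and correlations between arrays lay between 0.946 and 0.971 across tested probe sets.

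Each of the 38535 probe sets was named through the platform annotation of the array, which can be old: 27178 probe sets had 1 gene symbol, 177 had several and were left unnamed, and 11180 were not in the annotation and are unnamed here. Gene symbols and chromosomes were taken from the RefSeq gene table of the GRCg7b assembly, by gene ID for 26863 probe sets and by a unique symbol for 308; 7 were not matched. The deposited values name no genome build, so only chromosome names and the order of genes are given, without coordinates.

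Values were analysed as log2(intensity + 16), keeping the deposited scaling. The 96 control probe sets and the lowest 40% of the other probe sets by mean over all 10 arrays were left out of tests, which left 23063 probe sets, 4848 of them without a gene name. A gene was read through its probe set with the highest mean, chosen without regard to sex, giving 10284 genes; no gene had called probe sets of opposite direction. Males were compared with females in limma 3.58.1 (lmFit and eBayes with a variance trend, R 4.3.3), with Benjamini-Hochberg adjustment and a threshold of 0.05. All ratios of single genes are male minus female on the log2(intensity + 16) scale, which understates changes of dim probe sets.

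Values with 1 number per array, such as the median of Z genes minus the median of autosomal genes, were compared by a two-sided exact permutation test over the 252 arrangements of 5 and 5 arrays, whose smallest possible p is 0.00794. Genes on Z were put in their annotated order and divided into 10 groups, whose variance was set against 10000 shuffles of gene order. The 10 measured genes on each side of DMRT1 were set against the other Z genes by 10000 random draws, whose smallest p is 1e-04. The means of groups of genes along Z, of the neighbours of DMRT1 and of runs of genes have each array's median of autosomal genes subtracted. Bootstrap intervals cover 95% over 2000 draws of genes. Gene lists were tested with camera at a preset correlation of 0.01 over autosomal genes, with Z and W members left out and at least 5 measured members, and again with an estimated correlation and with fry. The 20 lists tested covered contraction, calcium handling, metabolism, ribosomal proteins, cell cycle, matrix, the other cell types of the heart, atrial and ventricular genes, neighbouring tissue, stress, sex steroid and cardiac transcription genes. RNA quality was read from the 3′ and 5′ control probe sets of actin and GAPDH.

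The genes to be named were set by rule before the data were examined: up to 6 W genes by level in females; the 12 largest Z ratios, the 8 largest female-higher ratios outside W and the 10 largest autosomal ratios among called genes whose arrays did not overlap between sexes; the 3 largest ratios of each gene list; and DMRT1, MEF2C, VCAN, GHR, LPL and CHD1. Up to 2 unnamed probe sets per direction could be described. Genes named outside this rule are said to be so where they appear. Lists, tests and most alternatives were also set before the data were examined.

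Alternatives covered the replicate block, quantile normalization, centring on autosomal genes, no filter and a filter at 60%, pseudocounts of 1, 64 and, added later, 1 that was 16 times larger than 16, each array left out, array weights, other variance priors, a fold of at least 1.2, an ordinary test per probe set, the mean of a gene's probe sets, means in place of medians, other list tests, 20 groups along Z and 5 level groups. The procedure was tested on simulated data for the male against female comparison, with 23063 probe sets. It called 28%, 56%, 82% and 96% of probe sets changed by a log2 value of 0.3, 0.6, 1 and 2, and 17 of 22005 unchanged ones. A Z shift of 0.4 was recovered as 0.392, and camera called the shifted list and 1 other.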

Results

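Whole hearts of chicken embryos were profiled on 10 arrays, 5 from pools of male RNA (male A to E) and 5 from pools of female RNA (female A to E). In birds, females carry a Z and a W chromosome and males carry a pair of Z chromosomes, so the design asks which genes of the embryonic heart differ between the sexes and how far Z-linked expression follows Z copy number. Array medians lay between 605 and 735 intensity units, with a mean of 638 ± 33.4 in males and 661 ± 53.6 in females (SD, n = 5 each).

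The sex labels were first set against genes annotated on W. HINTW, a W-linked relative of the HINT1 nucleotide hydrolase, had a mean intensity of 122990 in female pools and 127 in male pools, a log2 difference of -10.11 ± 0.40 (SE, limma adjusted p = 3e-09, n = 5 per sex). HNRNPKL, the W relative of the RNA-binding protein gene HNRNPK, averaged 8111 in females and 233 in males. UBE2R2L, a relative of a ubiquitin-conjugating enzyme gene, averaged 5531 and 206. The uncharacterised genes LOC430910 and LOC107049459 averaged 20826 and 6596 in females against 301 and 416 in males. Of 12 W-annotated genes above the filter, 9 were called higher in females. The male values are dim and the deposited values used here carry no detection call, so the W ratios depend on background and on the pseudocount.

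**Figure D1:**
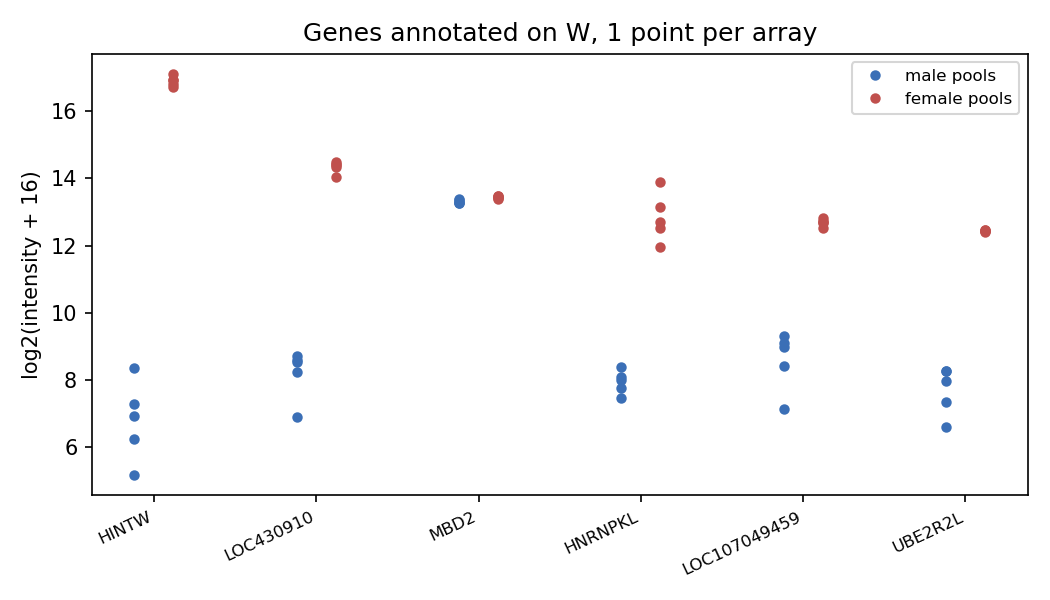
Log2(intensity + 16) of the 6 W-annotated genes with the highest female level, 1 point per array, male pools in blue and female pools in red. The 5 female arrays lie above the 5 male arrays for each gene, by 10.11 on average for HINTW and by a mean of only 0.14 for MBD2, which did not pass the test.

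MBD2, a methyl-DNA-binding protein gene that the GRCg7b table places on W, was expressed at 10145 in males and 11146 in females, a log2 difference of -0.14 ± 0.05 that did not pass the threshold (limma adjusted p = 0.419). NEDD4L, a ubiquitin ligase gene also placed on W there and singled out after its values were seen, was higher in males by 0.58 ± 0.08 (limma adjusted p = 0.000429). LOC425347, also singled out afterwards, differed by 0.03 ± 0.21 and was not called. These were the 3 W-annotated genes above the filter that were not called higher in females. Males carry no W, so the male signal of MBD2, and that of NEDD4L at 8009, cannot come from W. The W placement therefore does not describe what these probe sets read in males. Whether they also read a W transcript in females was not tested.

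Across all tested probe sets, 407 of 23063 passed the threshold, 348 higher in males and 59 higher in females, and 2098 had an unadjusted p under 0.05. At the level of genes, 229 of 10284 were called, 205 higher in males and 24 higher in females. Z held 201 of the male-higher genes, 98.5% of those on Z or autosomes (Fisher's exact test, two-sided, p = 1.05e-279). By chromosome class, 40.9% of 492 Z genes and 0.0307% of 9765 autosomal genes were called higher in males. Probe sets without a gene name added 55 male-higher and 23 female-higher calls, among them 11 that were higher in females by at least 4-fold. Arrays of both sexes did not overlap for 3.91% of all genes and 1.61% of autosomal genes, where chance gives 0.794%.

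Genes on Z were higher in males as a class, by less than a doubling. The median Z gene had a male minus female log2 ratio of 0.40, a 1.32-fold difference, with an interquartile range of 0.18 to 0.66, and 438 of the 492 (89.0%) lay above 0. The median autosomal gene lay at -0.03, with an interquartile range of -0.12 to 0.06, and 41.5% of autosomal genes lay above 0. Among 30 autosomes with at least 20 genes, chromosome medians ran from -0.12 on chromosome 30 to 0.00 on chromosome 2. On each array, the median of Z genes minus the median of autosomal genes was 0.13 ± 0.02 in males and -0.35 ± 0.06 in females (SD, n = 5 each), a difference of 0.48 or 1.40-fold (exact permutation test, p = 0.00794). This is the smallest p that these arrays can give, and all 5 male arrays lay above all 5 female arrays.

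**Figure D2:**
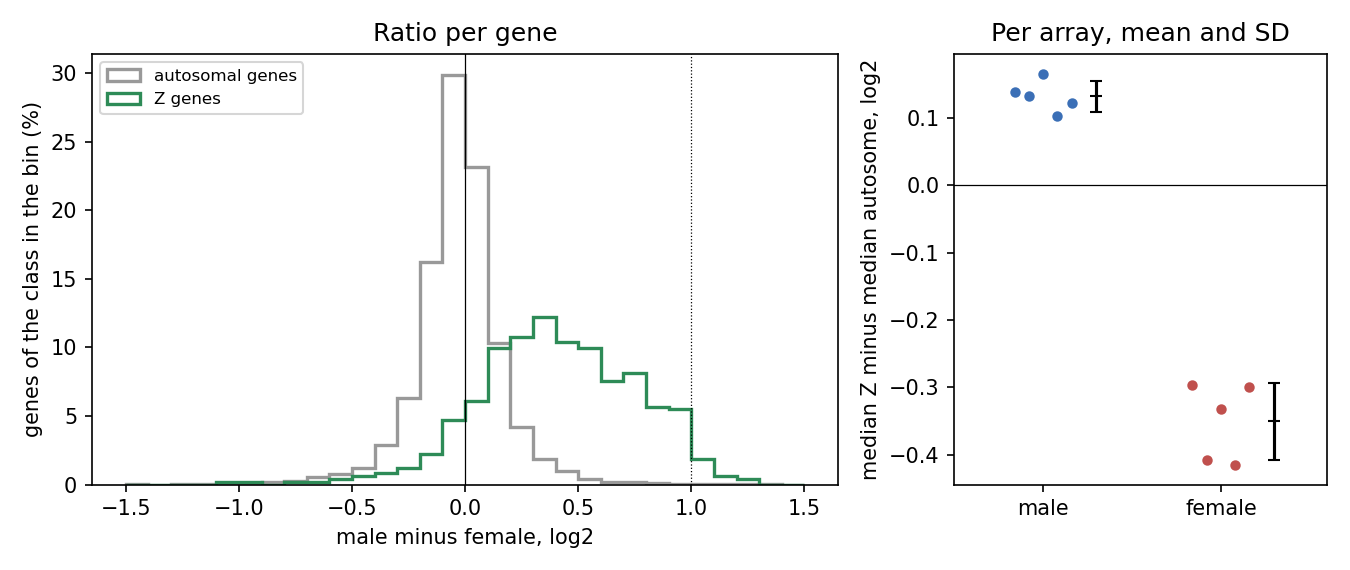
Left, percentage of autosomal (grey) and Z genes (green) in bins of male minus female log2 ratio, with lines at 0 and at a doubling; ratios beyond the axis are not drawn. Right, median Z minus median autosomal log2 level per array, with the mean and SD of 5 arrays: male arrays lie between 0.10 and 0.17 and female arrays between -0.42 and -0.30.

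The size of the difference varied widely between Z genes. The male over female fold was under 1 for 54 genes, 1 to 1.2 for 109, 1.2 to 1.5 for 174, 1.5 to 2 for 141 and at least 2 for 14. The 95% interval of the log2 ratio lay below 1, a doubling, for 394 genes (80.1%), and for 218 of the 492 it lay between 0 and 1 without reaching either. Another 82 intervals lay above 0 and included 1, 166 included 0 and lay below 1, 16 included both and 10 lay below 0.

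Among called Z genes whose arrays did not overlap between the sexes, the 12 with the largest ratios all had estimates above a doubling. They were picked for the size of these estimates. Every interval of a Z gene counted in the preceding paragraph included a doubling or lay below it. The estimates therefore do not show that any of these genes exceeded a doubling. PIK3C3, a phosphatidylinositol 3-kinase gene of autophagy and endosomal traffic, was 2.36-fold higher in males, with a log2 ratio of 1.24 ± 0.24 (SE, n = 5 per sex, limma adjusted p = 0.0109). ZDHHC21, a palmitoyltransferase gene, was 2.34-fold higher. IFT74, of intraflagellar transport, was 2.25-fold higher. The DNA repair gene SLF1 was 2.24-fold higher. SPTLC1, a subunit of serine palmitoyltransferase in sphingolipid synthesis, was 2.16-fold higher at a log2 ratio of 1.11 ± 0.07 (limma adjusted p = 4.13e-07). NMRK1, a nicotinamide riboside kinase gene, and ARSK, an arylsulfatase gene, were both 2.10-fold higher. LYRM7, an assembly factor of respiratory complex III, was 2.07-fold higher, as was the complement gene C7. SRFBP1, SMC2 of the condensin complex and the centrin gene CETN3 were 2.05-fold, 2.05-fold and 2.03-fold higher. ZDHHC21 and LYRM7 no longer passed with the mean of their probe sets, at 0.76 (adjusted p = 0.0788) and 0.44 (adjusted p = 0.171).

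Of the Z genes fixed beforehand for their roles, LPL and VCAN were called. LPL, the lipoprotein lipase gene, was higher in males by 0.49 ± 0.06, a 1.41-fold difference (limma adjusted p = 0.000186). VCAN, encoding the matrix proteoglycan versican, was higher by 0.44 ± 0.08, or 1.36-fold (limma adjusted p = 0.00364; 0.0549 with an ordinary per-probe-set test). The cardiac transcription factor gene MEF2C had a ratio of 0.54 ± 0.20, the growth hormone receptor gene GHR 0.29 ± 0.09 and the chromatin remodeller gene CHD1 0.37 ± 0.15, none past the threshold (adjusted p = 0.367, 0.224 and 0.456). Of 36 measured genes in a list of Z genes fixed from textbook knowledge, 13 were called higher in males over all genes tested and 19 when adjusted over the list alone, with a median ratio of 0.24.

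The Z ratio was lower among dim genes. In 3 equal groups by mean level, the median ratio was 0.29 in the dimmest, 0.46 in the middle and 0.49 in the brightest group (95% bootstrap interval 0.40 to 0.56), while autosomal medians at the same levels were -0.04, -0.02 and -0.03. Across the 492 Z genes, which are not independent replicates, ratio and level had a Spearman correlation of 0.206 (p = 3.92e-06). With the lowest 60% of probe sets left out the correlation was 0.0502 (p = 0.331). It was 0.323 with no filter and, with a pseudocount 16 times larger that was chosen after seeing the data, also 0.323.

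Most Z genes that have a W relative were also higher in males. Of 16 such genes measured, 13 were called higher in males, and their median ratio was 0.49 against 0.39 for other Z genes. SPIN1, RASA1, TXNL1 and HNRNPK, named after their values were seen, had ratios of 0.94, 0.90, 0.72 and 0.68. The 3 that were not called, of which the last pair were also named afterwards, were CHD1, the ATP synthase gene ATP5F1AZ at 0.16 ± 0.06 and ZSWIM6 at -1.03 ± 0.30; ATP5F1AZ passed after quantile normalization, at 0.20 (limma adjusted p = 0.000475). Per array, their median minus that of other Z genes was 2.39 ± 0.06 in males and 2.11 ± 0.07 in females (SD, n = 5 each), a difference of 0.28 (exact permutation test, p = 0.00794). With each gene centred first, a setting chosen after seeing the data, the difference was 0.09 (exact p = 0.0397). It was 0.18 with no filter (exact p = 0.0238) and 0.43 with the stricter filter (exact p = 0.00794). Genes with a W relative were brighter than other Z genes on every array, with medians higher by 2.01 to 2.46. The brightest of the 3 level groups of Z genes also had a median ratio of 0.49. A link with the W relative therefore cannot be told apart from level here.

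Along Z, each group of genes was higher in males, with each array's autosomal median subtracted. In 10 groups of 49 or 50 genes in annotated order, mean ratios ran from 0.27 in the fifth group, ENC1 to SLC24A2, to 0.54 in the seventh (exact permutation test with Benjamini-Hochberg adjustment, adjusted p = 0.00794 for each). The SD of the 10 group means was 0.0796, larger than in most shuffles of gene order (permutation p = 0.0116); with the stricter filter it was 0.0691 (permutation p = 0.0589).

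The 10 measured genes on either side of DMRT1, a testis-determining gene beside which a region is hypermethylated in males, had a mean ratio of 0.11 against 0.45 for the other 472 Z genes, both less the autosomal median. The difference of -0.34 had p = 1e-04 by random draws of genes, the smallest they can give, and p = 0.00794 by the exact permutation test over arrays; with the stricter filter it was -0.22 (exact p = 0.00794). Of these 20 genes, named after their values were seen, 6 were called higher in males, with TNPO1, PTCD2, MRPS27, CBWD1, SMARCA2 and PUM3 at 0.73, 0.66, 0.53, 0.59, 0.53 and 0.42. TNPO1 did not pass with the mean of its probe sets (0.41, adjusted p = 0.255). Called higher in females were SLC1A1, a glutamate transporter gene, at -1.78 ± 0.37 (limma adjusted p = 0.0175), and AK3, a mitochondrial adenylate kinase gene, at -0.56 ± 0.07 (adjusted p = 0.000231). SLC1A1 lost the call without female C (adjusted p = 0.0542) and without female D (adjusted p = 0.0662), and with the ordinary per-probe-set test (adjusted p = 0.0874). The other 12 did not pass, among them PGM5 at -0.01, KANK1 at -0.28, the lipoprotein receptor gene VLDLR at -0.15 and JAK2 at 0.07. The share called male-higher, 6 of 20 against 195 of 472, did not differ (Fisher's exact test, two-sided, p = 0.361). DMRT1 itself had a ratio of -0.63 ± 0.23 and was not called (adjusted p = 0.332). The lowest run of 20 genes on Z, PGM5 to GLDC, held 13 of these neighbours and had a mean of -0.03 less the autosomal median, where the median run had 0.45 and the lowest run not overlapping it 0.23.

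**Figure D3:**
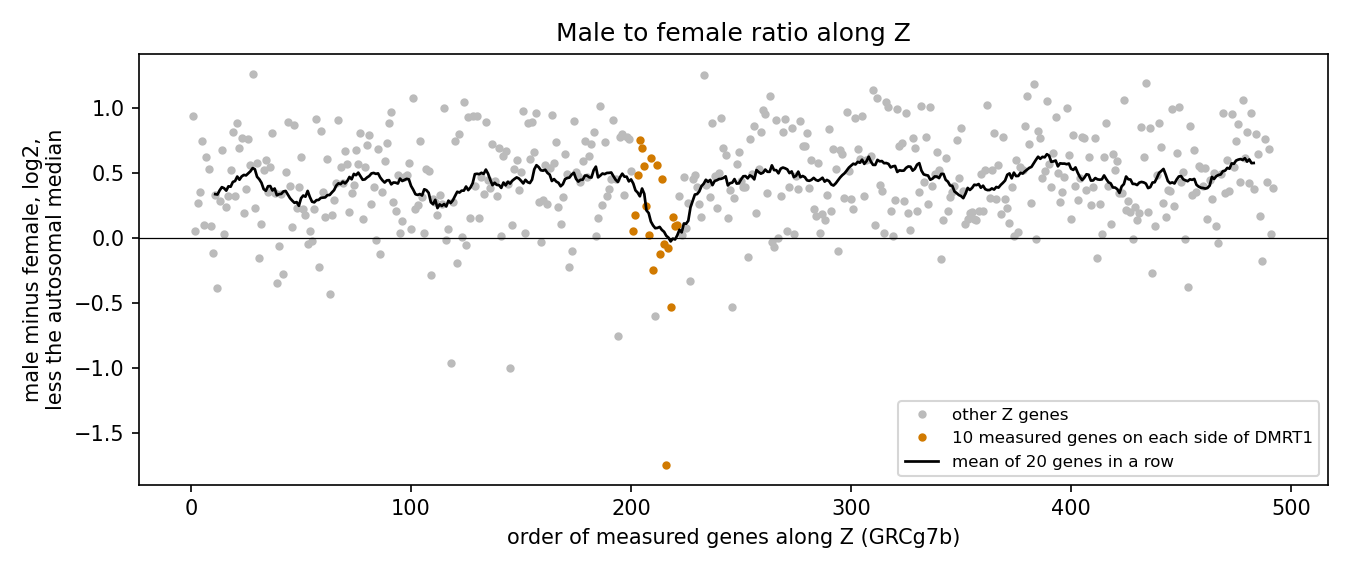
Male minus female log2 ratio, less the autosomal median, of each of the 492 measured Z genes (points) in annotated order, with the 20 measured neighbours of DMRT1 in orange and the mean of 20 genes in a row as a line. The line is lowest, at -0.03, in the run PGM5 to GLDC.

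Few autosomal genes differed: 16 of 9765 were called, 13 higher in females and 3 higher in males, and 708 (7.25%) had an unadjusted p under 0.05. PLA2G5, a secreted phospholipase gene on chromosome 21, averaged 3116 in females and 469 in males, a ratio of -3.02 ± 0.42 (limma adjusted p = 0.000488, n = 5 per sex). The uncharacterised gene LOC426626 on chromosome 28 was at -0.75 ± 0.08 (adjusted p = 2.84e-05), and SPG20, the spartin gene, at -0.72 ± 0.10 (adjusted p = 0.000582). NTPCR, a nucleoside triphosphatase gene, was at -0.60, and TIGAR, a regulator of glycolysis, at -0.54. The lysosomal peptidase gene TPP1 was at -0.39 and COQ9, of ubiquinone synthesis, at -0.37. With the mean of their probe sets, LOC426626, SPG20 and COQ9 had -0.35, -0.38 and -0.12 and did not pass (adjusted p = 0.202, 0.0799 and 0.768). Higher in males were the calcium channel gene TRPV6 at 0.71 ± 0.11 (adjusted p = 0.00106), ANKRD26 at 0.48 and, named because it completes the 3, the nuclear receptor gene NR2C1 at 0.36. ANKRD26 and NR2C1 did not pass with the mean of their probe sets (0.30 and 0.19, adjusted p = 0.611 and 0.305). Of 10 fits that left out 1 array, TPP1 lost the call in 7, without any of A to C of either sex or without female D (adjusted p up to 0.137). ANKRD26 lost it in 5, without male A, B or C or female C or D (adjusted p up to 0.0716), and COQ9 in 3, without female B, male E or female E (adjusted p up to 0.054). With no variance trend TPP1, COQ9 and NR2C1 did not pass (adjusted p = 0.159, 0.0908 and 0.0619), and with the ordinary test TPP1, COQ9 and ANKRD26 did not (adjusted p = 0.166, 0.0802 and 0.051). Without male B, 10 autosomal genes were called, 8 of them higher in females, and without female A, female B or male D the male-higher genes numbered 6.

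Contractile genes showed no called difference in the main fit, which has no replicate block. None of 27 autosomal sarcomere genes passed (0 called by limma, 0 when adjusted over the list alone), and the largest ratios were those of the myosin light chain gene MYL1 at -0.34 ± 0.09, ANKRD1 at -0.23 ± 0.14 and the troponin gene TNNI1 at -0.09 ± 0.08. The list had a median of -0.04 (camera adjusted p = 0.498, or 0.921 with an estimated correlation). Without female B, MYL1 passed at -0.41 (limma adjusted p = 0.031), and without male A the list passed with a median of -0.08 (camera adjusted p = 0.00644). With the letter as a replicate block, MYL1 passed on all 10 arrays (limma adjusted p = 0.00747). Of 21 calcium handling and ion channel genes, PLN was called, over all genes and when adjusted over the list alone. PLN encodes phospholamban, the inhibitor of the sarcoplasmic calcium pump, and averaged 2101 in females and 1464 in males, a ratio of -0.52 ± 0.11 (limma adjusted p = 0.0238). That call was lost in 7 of the 10 fits that left out 1 array, those without any of A to C of either sex or without female D, with adjusted p up to 0.0709. PLN also lost the call with the letter as a replicate block (limma adjusted p = 0.0696). The calcium channel gene CACNA1G and SLN, encoding sarcolipin, were at -0.40 ± 0.49 and -0.27 ± 0.20. This list had a median of -0.05 (camera adjusted p = 0.498).

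Autosomal genes of oxidative phosphorylation were slightly lower in males as a list, with a median of -0.08 over 41 genes, 38 of them below 0 (camera adjusted p = 1.74e-05; adjusted p = 0.669 with an estimated correlation). Counts below 0 are to be read against all autosomal genes, of which 41.5% lay above 0. ATP5J2 of the ATP synthase was at -0.24, and the complex I subunit genes NDUFB5 and NDUFS3 were at -0.23 ± 0.06 (limma adjusted p = 0.0552) and -0.20. No single member passed over all genes tested by limma, 6 had an unadjusted p under 0.05 and 2 passed when adjusted over the list alone. After quantile normalization the list's median was -0.04, with 33 below 0 (camera adjusted p = 0.0175), and NDUFB5 passed at -0.18 (limma adjusted p = 0.0216). NDUFB5 also passed without male A (0.0367), without female A (0.0269), with the stricter filter (0.0437) and with the robust prior (0.0419). The 4 Z members had a median of 0.40, and 3 were called higher in males, namely NDUFS4 at 1.02, COX7C at 0.47 and ATP5I at 0.33, named after their values were seen.

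Fatty acid oxidation and lipid uptake genes had a median of -0.07 over 19, 15 of them below 0 (camera adjusted p = 0.0492; adjusted p = 0.669 with an estimated correlation). The largest ratio was against this direction, that of the electron transfer flavoprotein gene ETFA at 0.32 ± 0.37. It was followed by the fatty acid binding protein gene FABP4 at -0.30 ± 0.32 and the carnitine carrier gene SLC25A20 at -0.20 ± 0.05 (limma adjusted p = 0.0507). None passed over all genes tested by limma, 3 had an unadjusted p under 0.05 and 1 passed when adjusted over the list alone. The list lost its call without female A (camera adjusted p = 0.166), male B (0.244), female B (0.237), male D (0.0935), male E (0.0627) or female E (0.0561), after centring on autosomal genes (0.0888), after quantile normalization (0.177), with no filter (0.0633), with a pseudocount of 64 (0.0515) or 16 times that of 16 (0.0573), and with the mean of a gene's probe sets (0.38). SLC25A20 passed without female B (limma adjusted p = 0.0498), with the stricter filter (0.0348), array weights (0.0461), the robust prior (0.0482) and the ordinary test (0.017). Glycolysis and lactate genes, 19 in number, had a median of -0.05 (camera adjusted p = 0.097), with ENO2, SLC16A3 and PFKL at -0.29, 0.20 and -0.19. This list passed without male A (camera adjusted p = 0.0253), male C (0.0154) or female C (0.0268).

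Ribosomal protein genes had a median of -0.06 over 51, 47 of them below 0 (camera adjusted p = 0.00781; adjusted p = 0.766 with an estimated correlation). The largest ratio was again against this direction, RPS13 at 0.72 ± 0.58 (limma adjusted p = 0.784), followed by RPL12 at -0.20 and RPL15 at -0.16. The RPS13 probe set was dim, averaging 898 in males and 755 in females. Its ratio rests on low log2 levels in female A, at 6.51, and female E, at 8.34. No member was called by limma over all genes or when adjusted over the list alone, and 1 had an unadjusted p under 0.05. After quantile normalization the median was -0.02, with 36 below 0 (camera adjusted p = 0.5). With the mean of a gene's probe sets the call was also lost (0.063). It was lost without male B (camera adjusted p = 0.102), female B (0.203), male C (0.837, median -0.03) or female D (0.541, median -0.03), and without male A the median was -0.11.

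Extracellular matrix and fibroblast genes were higher in males as a list, with a median of 0.13 over 27 autosomal genes, 22 of them above 0 (camera adjusted p = 1.74e-05; adjusted p = 0.669 with an estimated correlation). LUM, encoding the matrix proteoglycan lumican, was at 0.33 ± 0.08 (limma adjusted p = 0.051), and FBLN5 and ELN of elastic fibres were at 0.53 ± 0.44 and 0.49 ± 0.45. None was called by limma over all genes, 6 had an unadjusted p under 0.05 and 1 passed when adjusted over the list alone. LUM passed without male A (limma adjusted p = 0.0119) or male C (0.0436), after quantile normalization (0.0496) or centring (0.035), and with the stricter filter (0.0382), the robust prior (0.0383) or a larger pseudocount (0.0491 at 64). It also passed with the letter as a replicate block (limma adjusted p = 0.0476). The list's median was 0.06 without female A, 0.07 without male B and 0.08 without female B, and the direction held after quantile normalization and centring. Of 20 lists, 4 passed with camera at the preset correlation, 7 without male A and 2 without male B or without female B, and 29 of 100 splits of the arrays gave 4 or more. With Z and W members kept, only the matrix list passed. With fry, 0 lists passed after adjustment and 4 had an unadjusted p under 0.05; with an estimated correlation, 0 passed and 0 had an unadjusted p under 0.05.

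None of the other 16 lists passed (camera adjusted p of at least 0.097), and of the autosomal members of all 20 lists, PLN alone was called by limma over all genes, while 6 passed when adjusted over the list alone, 1 of them epicardial. Cell cycle genes had a median of -0.02 over 37 and a mean of 0.00 with the test's direction up, and CENPF, CENPE and CDC45 were at 0.24, 0.23 and 0.21. Their Z member CKS2, named after its value was seen, was called higher in males at 0.90. Endothelial and endocardial genes had a median of -0.06, with TAL1, TIE1 and SOX18 at 0.70, -0.22 and -0.18. Smooth muscle and pericyte genes had a median of 0.03, with MYH11, ABCC9 and RGS5 at 0.51, 0.19 and -0.10. The epicardial list had a median of -0.04 over 7, with UPK1B at -1.49 ± 0.44 (limma adjusted p = 0.164), MSLN at 0.34 and TCF21 at -0.23. Atrial genes had a median of -0.05, with SLN, KCNJ3 and KCNA5 at -0.27, -0.21 and -0.09. Ventricular genes had a median of -0.02, with HEY2, IRX5 and MYH15 at -0.51, 0.12 and -0.05.

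Stress and immediate early genes had a median of -0.02, with HSPH1, HSP90AB1 and ATF3 at 0.20, -0.15 and 0.13. Their Z member DNAJA1, also named afterwards, was called at 0.24, a call lost in 9 of the 10 fits that left out 1 array, all but that without female A (adjusted p up to 0.121), with no filter (0.0529) and with no variance trend (0.17). Sex steroid and gonadal genes had a median of -0.03 and a mean of 0.06, with CYP17A1 and SRD5A1 of steroid synthesis at 0.93 and 0.90 and the receptor gene FSHR at -0.69, none past the threshold. Cardiac transcription and signalling genes had a median of 0.00 and a mean of -0.04 with the test's direction up, and HEY2, TGFB1 and ERBB4 were at -0.51, -0.35 and -0.20.

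Markers of other cells and signs of RNA quality did not pass the threshold on all 10 arrays in the main analysis, which has no replicate block. The erythroid list had a median ratio of -0.13 over 13 genes (camera adjusted p = 0.097), with TAL1, CA2 and HBZ at 0.70, 0.69 and -0.52. The list passed without male A, at a median of -0.18 (camera adjusted p = 0.000635), and without female C, at -0.16 (0.0272). With the letter as a replicate block it also passed (camera adjusted p = 0.0382). With an estimated correlation and no block, its camera adjusted p on all 10 arrays was 0.766. Its median level per array was 13.78 ± 0.21 in males and 13.96 ± 0.11 in females (SD, n = 5 each, exact permutation p = 0.135, adjusted p = 0.533 over 6 measures). Leukocyte genes had a median of -0.07, with C1QC, CD4 and PTPRC at -0.77, 0.56 and -0.42, and nerve and neural crest genes -0.07, with CHGA, SNAP25 and SYT1 at -0.47, -0.43 and -0.27. Genes of liver, lung, cartilage and skeletal muscle had a median of -0.03 and a mean of 0.11, with ALB, TNNT3 and COL9A1 at 0.67, 0.50 and 0.33. Their median level was 10.27 ± 0.44 in males and 10.02 ± 0.18 in females (exact permutation p = 0.278, adjusted p = 0.533). The 3′ minus 5′ difference of actin was 0.70 ± 0.07 in males and 0.68 ± 0.10 in females (exact permutation p = 0.81), and that of GAPDH was -0.14 ± 0.06 and -0.19 ± 0.05 (exact permutation p = 0.206, adjusted p = 0.533).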

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

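The tests of array scaling and of the DMRT1 region without SLC1A1 were chosen after the results were seen. Of 284 groups of 5 arrays examined, 1 per sex for each named gene and array measure, 12 held an array far from the other 4, where chance gives about 14.2. Male A stood apart in 4 of them. For NMRK1, FSHR and DMRT1 it was the lowest, with log2 levels of 11.39, 7.78 and 8.90, and for RPS6 it was the highest, at 17.57. Female D was lowest for SPTLC1, at 11.73, and for CD4, at 7.95 against 10.16 to 10.68. Male B was highest for CDC45, at 13.21, male C highest for ABCC9, at 15.13, and male E lowest for LOC430910, at 6.88. Female B was lowest for RASA1, at 11.46, female C lowest for CKS2, at 12.45, and female E highest for ERBB4, at 11.79. RPS6, RASA1 and CKS2 were named after their values were seen.

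Splits of the 10 arrays into other groups of 5 tested whether chance can give as many calls. In 1 of 100 splits, the real one, as many as 407 probe sets were called, and the highest of the others gave 19. The real split was also the only 1 of 100 to reach 229 genes, with 8 as the highest of the others, and the only 1 of 100 to reach 16 autosomal genes, again with 8 as the highest other. None of the other splits drawn came near 407 probe sets or 229 genes, so these counts follow the sex labels. Each other split mixes the sexes, so Z and W differences widen the spread within its groups and hold its calls down. The splits therefore do not measure how many of the calls are due to chance. The autosomal count is not settled by this test. The adjusted threshold loosens as more Z and W probe sets are called, and the real split had many more of these. Single autosomal calls can therefore be chance. Chance is not excluded for the 4 gene lists past the threshold, since 29 of 100 splits gave 4 or more and the highest other gave 10.

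The Z ratio lay under a doubling. Compression of ratios in dim probe sets is argued against as the whole cause, since the brightest of the 3 level groups had a median with an upper 95% bound of 0.556, far from 1. The median autosomal gene lay at -0.03, so centring on autosomal genes could move the Z ratio only a little. The deposited arrays had already been brought to 1 common level, which by itself keeps that median small. The median is therefore no test of array scaling. Neither is the Z ratio's upper bound of 0.464 after centring, over draws of genes. The Z ratio holds relative to autosomal genes, and an offset removed by the scaling stays open. Compression that acts on bright probe sets alike, and differences in pool makeup, were not tested and stay open. A sex difference in the regulation of Z genes stays open and untested, since a ratio does not tell raised female levels from lowered male ones.

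The low ratio around DMRT1 was set against a pair of explanations. The region was not dim, with a mean log2 level of 11.66 against 11.6 for other Z genes, which argues against low expression. Level-matched draws thus had little room to differ from the other Z genes, and averaged 0.45. The region's mean of 0.11, less the autosomal median, lay below them (permutation p = 1e-04, the smallest they can give), which adds little. A single gene carrying the region is also argued against, since without SLC1A1 the region still differed by -0.24 (permutation p = 0.003). Probe sets that read other transcripts stay open. A biological candidate is the region hypermethylated in males that lies beside DMRT1, for which the arrays give no test.

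Of the 13 autosomal genes called higher in females, 6 had another tested probe set. MGARP and FBXO9 among them were named after their values were seen. In 4 of the 6 (LOC426626, SPG20, COQ9 and MGARP) the others' median ratio was near 0 or positive, at 0.05, -0.03, 0.12 and 0.24. Probe sets that read different transcripts, or a transcript other than the named gene, would give this. Calls made by chance would give it too, and these values do not tell them apart. NTPCR was at -0.60 with another probe set at -0.77, and FBXO9 at -0.25 with another at -0.26. For those genes this argues against a single probe set alone reading a different transcript. It stays open whether both probe sets of a gene read the same other transcript. The other FBXO9 probe set was not called. Of 10 fits that left out 1 array, FBXO9 lost its call in 3, without male B, female C or male E (limma adjusted p up to 0.0591). MGARP lost its call in 9, all but that without male C (up to 0.124). Both lost it with no variance trend (0.116 and 0.238). The other 7, PLN and PLA2G5 among them, had no other probe set, so a different transcript stays open for them. A sex difference in these genes stays open for all 13.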

How the results depend on the processing

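A pseudocount 16 times larger, genes centred before medians were taken, and the region without SLC1A1 were alternatives chosen after seeing the data. The counts of 407 probe sets and 229 genes stayed within 1.5 times, and the Z difference of 0.48 kept its direction, under every alternative run for them; 299 to 407 of the 407 probe sets were shared with each alternative. Pools with the same letter deviated together weakly, with correlations from 0.0025 to 0.207, where the highest between other letters was 0.092. Of 5 males, 4 correlated best with their own letter, so a shared effect of the letter is not excluded. The sources used here do not say that the letters pair samples, and the main fit has no block. With the letter as a replicate block, 405 probe sets were called, 366 of them shared. In that block the Z difference (0.48), the difference of Z genes with a W relative (0.28) and the DMRT1 region per array (-0.34) had exact p = 0.0625, the smallest that 5 pairs can give, so 0 of 10 groups along Z could pass, and 9 autosomal genes were male-higher. There MYL1 (adjusted p = 0.00747), LUM (0.0476) and the erythroid list (0.0382) passed, and PLN (0.0696), RPL17 (0.0724), KAZN (0.0527), SREBF2 (0.0903) and the fatty acid list (0.0612) did not. Autosomal calls, 16, were 27 with the stricter filter, which tests fewer genes. Female-higher ones, 13, were 22 there and with the mean of a gene's probe sets, 21 with the ordinary test and 20 after quantile normalization. Male-higher ones, 3, were 5 after centring, with the pseudocount of 64 and the larger 1, with the robust prior and with the stricter filter, and 1 with the mean of probe sets. Leaving out 1 array gave 10 to 21 autosomal calls, 2 to 6 male-higher and 8 to 15 female-higher, and 2 to 7 lists. The 4 lists became 0 with an estimated correlation, 0 with fry, 1 with Z and W members kept, and 2 after quantile normalization or with the mean of probe sets. The stricter filter left 5 female-higher W genes of 9, since fewer pass it, moved the median Z ratio from 0.40 to 0.45, the spread along Z to 0.0691 and the correlation with level to 0.0502; the pseudocount 16 times larger moved the median Z ratio to 0.34. With 20 groups along Z, all 20 passed. MGARP turned from -0.28 to 0.067 with the mean of its probe sets (adjusted p = 0.947). Where no construction is named, the cause was not tested. Called genes followed through the alternatives numbered 59, with KAZN, SREBF2, SRA1 and LOC374195, which were chosen after their values were seen and are not described elsewhere. Of their 1412 values, 1296 kept direction and side, 115 lost the call and 1 reversed. Dim probe sets and the absence of detection calls limit W ratios and dim Z genes.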

Other observations

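The gene groups and genes in this part were chosen after the data were examined. Of mitochondrial ribosomal protein genes, whose products assemble into 1 particle, all 5 measured Z members were called higher in males, with MRPS30, MRPL17, MRPL50, MRPS36 and MRPS27 at log2 ratios of 0.97, 0.88, 0.74, 0.55 and 0.53. The 59 autosomal members had a median of -0.10, 50 of them below 0, with 0 called by limma and 11 at an unadjusted p under 0.05. Of all autosomal genes, 41.5% lay above 0. The autosomal median was -0.10 after quantile normalization and -0.09 after centring on autosomal genes. Whether these members differ from other autosomal or other Z genes was not tested. Among the 4 Z members of the cytosolic ribosome, RPL17 was called at 0.26, while RPS6, RPS23 and RPL37 were at 0.12, 0.12 and 0.04 and did not pass; after quantile normalization RPS6 and RPS23 passed at 0.16 and 0.14 (adjusted p = 0.0126 and 0.0123). RPL17 lost its call in 9 of the 10 fits that left out 1 array, all but that without male C (adjusted p up to 0.095), with no filter (0.105), with no variance trend (0.233) and with the ordinary test (0.11).

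Of 492 Z genes, 10 had a 95% interval below 0. They were KANK1, DMRT1, VLDLR, SLC1A1, AK3 and GLDC, the last at -0.36 ± 0.12, and the cardiac progenitor gene ISL1 at -0.99 ± 0.39, ZSWIM6 at -1.03 ± 0.30, FAM169A at -0.78 ± 0.23 and the mitochondrial carrier gene SLC25A51 at -0.20 ± 0.06. Of the 10, SLC1A1 and AK3 passed the threshold, and ZSWIM6 passed with the mean of its probe sets (-1.23, adjusted p = 0.0199). The 2 unnamed probe sets with the largest female-higher ratios averaged 7379 and 4313 in females against 103 and 51.8 in males, a separation like that of the W genes, and carry no gene name here.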
